A study of Homo sapiens with 24 samples.

How the data were processed

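The series holds RNA-seq of KYSE 150 and KYSE 510 cells in 8 groups of 3 libraries, 24 in all. Per the labels, messenger RNA libraries were made with a SMARTER mRNA-Seq kit from 1.3 µg total RNA. The groups are cells with a control guide, cells treated with cisplatin for 2 days, cells with MAGEA6 knocked out, and knockout cells treated with cisplatin. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values here measure only the spread between these libraries, which may be technical. Nor do they say which guide the cells treated with cisplatin alone carried. The protocol names 40 and 8 µM cisplatin and writes both beside KYSE 150, so no dose was assigned to a line.

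The authors' processing notes name CASAVA and HISAT2, without versions, and the genome build mm10, although the organism and the gene names in the table are human. The counter and the annotation are not given in the sources used here. The authors deposited whole-number counts for each gene locus of each library, which were used for every test. The same deposited table holds FPKM for the 24 libraries, which were not tested, and the p-values, log2 fold changes and calls of the authors' DESeq2 comparisons, which were only compared with the values found here. It has 25206 loci, of which 5276 carry an MSTRG identifier, the default prefix of loci assembled by StringTie, and 1727 had no count in any library. Loci without a gene name were tested but not named, and they held 1.51 to 5.74% of the counts of a library. Library totals ran from 3.27e7 to 3.96e7 counts. No 2 libraries of a group were copies of each other: the chi-square per gene between them was 7.73 or more, where counting noise alone gives about 1.

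Each line was analysed in its own fit of 12 libraries with 4 group means, because the lines differ widely at baseline. Counts were scaled with TMM, low counts were removed with filterByExpr, and contrasts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This left 16801 genes in KYSE 150 and 16925 in KYSE 510. Differences between lines came from 1 fit of all 24 libraries and 18575 genes. Standard errors are the absolute log2 fold change divided by the square root of F. In each line the contrasts were the knockout against sgNC without cisplatin, cisplatin against sgNC, the knockout with cisplatin against cisplatin alone, cisplatin within the knockout, and the interaction. The line differences were those of the untreated knockout effect and of the cisplatin effect against sgNC. A gene at 0 counts in every library of one group is given as a bound on its fold, with 3 counts per library as the floor, and in interactions and line differences without a size.

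The 34 gene lists were written from general knowledge before the data were examined, as were the contrasts, tests, thresholds and the alternative settings. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists of a contrast, again with the correlation estimated from the data, and with fry. Beside each count of list members past the genome-wide threshold stands the count when p-values were adjusted over the list alone. Genes were named by a rule fixed in advance: MAGEA6 and its tested paralogs. Then came the 6 largest rises and 6 largest falls of each comparison among genes past the threshold with a mean of at least 5 CPM in the higher group, non-overlapping libraries and a gene symbol that is not a clone name. For interactions and line differences it was 4 in each direction, and in each list described, up to 4 members with the smallest adjusted p. CDKN1A, GDF15, MDM2, CXCL8 and ATF3 could always be named. Some genes that met the rule are not reported here. Members that moved against their list, and MKI67, were named after their values were seen.

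Agreement between effects was measured as the correlation of log2 fold changes over all genes tested in both, using pairs of comparisons that share no library. Genes are not independent replicates, so no p-value is given for it. Genomic spans were taken from RefSeq genes of GRCh38.p14 and the GC content of transcripts from GENCODE v29.

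Alternatives tried were DESeq2 size factors or upper-quartile factors in place of TMM, no filter or a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0 or limma-voom as the test, the replicate number as a block, a fit of only the 6 libraries compared or of all 24, and leaving out each library in turn. List tests were repeated with DESeq2 size factors, the other filter, the block and, chosen after the results were seen, without 1 library. With 3 against 3 libraries an exact rank test cannot give a 2-sided p under 0.1, so none was used. A change of pseudocount was fixed only for a table without counts and was not run. The pipeline was tested on simulated data with known changes at the same depth. At most 67 genes were changed by each amount, far fewer than were called in the real comparisons. The share recovered depends on how many genes change, so the shares below need not hold there. For a true log2 change of 0.5, 1 and 2, edgeR recovered 40.3, 91.0 and 97.0% of changed genes in KYSE 150 and 53.7, 79.1 and 98.5% in KYSE 510, and for interactions 19.4, 71.6 and 89.4% and 31.3, 67.2 and 92.4%.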

Results

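Gene counts were available for 24 RNA-seq libraries of KYSE 150 and KYSE 510, established lines of esophageal squamous cell carcinoma. Each line was sampled in 4 groups of 3 libraries: cells with a control guide (sgNC), cells treated with cisplatin, cells with MAGEA6 knocked out (MAGEA6-KO), and knockout cells treated with cisplatin. MAGEA6 encodes a cancer-testis antigen of the MAGE-A family, and cisplatin is a platinum drug that crosslinks DNA. The question named by the series is what cisplatin does when MAGEA6 is depleted. Libraries held 3.27e7 to 3.96e7 counts. The labels do not say whether the cells given cisplatin alone carried the control guide. Knockout and control cells of a line may differ in more than MAGEA6. The design cannot tell such a difference from the loss of MAGEA6. The protocol names 40 and 8 µM cisplatin for 2 days and writes both doses beside KYSE 150, so the dose of each line is not known here. Log2 fold changes are given as estimate ± SE from edgeR with 3 libraries in each group, and levels in CPM (counts scaled to library size), mean ± SD, n = 3. A gene written as at a value without CPM has that log2 fold change in the comparison described.

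MAGEA6 mRNA was lower in MAGEA6-KO cells of both lines but was not lost. In KYSE 150 its level was 112 ± 10.9 CPM in sgNC cells, 19.6 ± 0.233 in MAGEA6-KO cells, 177 ± 12.4 with cisplatin alone and 106 ± 6.69 in MAGEA6-KO cells with cisplatin. In KYSE 510 the same groups held 2.08 ± 0.345, 0.827 ± 0.443, 5.43 ± 0.641 and 1.37 ± 0.212 CPM. Untreated, the knockout changed MAGEA6 by -2.52 ± 0.085 log2 in KYSE 150 (edgeR, adjusted p = 9.04e-12) and -1.33 ± 0.32 in KYSE 510 (adjusted p = 0.0142). Under cisplatin the difference was -0.74 ± 0.078 in KYSE 150 (edgeR, adjusted p = 3.06e-06) and -1.98 ± 0.31 in KYSE 510 (adjusted p = 0.000555). MAGEA3, a paralog of nearly identical sequence, fell by similar amounts untreated, -2.50 ± 0.090 in KYSE 150 and -1.82 ± 0.098 in KYSE 510. Reads of the 2 genes may have been shared and the values of either alone are uncertain. MAGEA4 rose by 0.88 ± 0.066 in untreated KYSE 150 knockout cells, whereas MAGEA2 and MAGEA2B, also close copies of each other, fell slightly (-0.33 ± 0.088 and -0.31 ± 0.091). MAGEA12 did not pass in KYSE 150 (-0.13 ± 0.073), nor did MAGEA9 and MAGEA9B in KYSE 510 (0.035 ± 0.12 and 0.16 ± 0.095). Of 13 tested MAGE and other cancer-testis genes in KYSE 150 the knockout lowered 8 of 13 (8 adjusted over the list alone), with a median of -0.33 (camera, adjusted p = 0.0214; adjusted p = 0.459 with an estimated correlation). A frameshift need not lower an mRNA, and the table holds no protein values, so loss of the protein could not be examined.

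**Figure D1:**
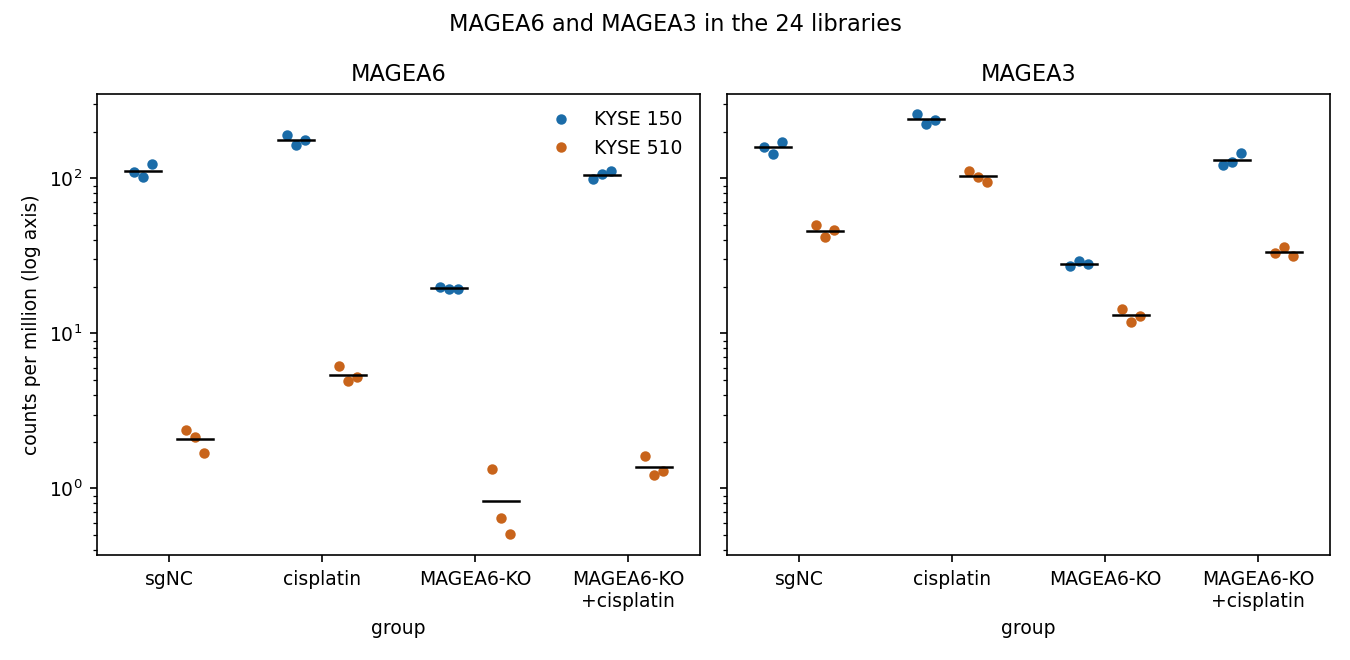
Levels of MAGEA6 and MAGEA3 in CPM in each of the 24 libraries, by group and cell line, on a log axis. Bars mark the group mean of 3 libraries.

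In untreated KYSE 150, transcripts of the cell cycle were several-fold higher, and those of basal keratinocytes several-fold lower, in MAGEA6-KO than in sgNC cells. The sgNC libraries stood apart from the 3 other groups of the line: MKI67, a marker of cycling cells, held 85.0 ± 18.4 CPM in them against 302 to 338 CPM in the other group means. ASNS of the stress response held 435 ± 53.2 CPM against 137 to 241, and KRT15 was higher in sgNC than in all 3. Genes of S phase and DNA replication rose in 44 of 44 genes (44 adjusted over the list alone), with a median of 2.12 log2, and genes of G2/M and mitosis in 41 of 42 genes (41 adjusted over the list alone), with a median of 2.30. Genes of interstrand crosslink and homologous recombination repair rose in 27 of 32 genes (27 adjusted over the list alone) (median 1.86). Basal keratinocyte genes fell in 23 of 25 genes (23 adjusted over the list alone) (median -2.08). With camera the 4 lists stood apart from other genes (adjusted p = 2.42e-60, 4.99e-72, 1.15e-20 and 9.09e-23). They also did when the correlation between genes was estimated (adjusted p = 0.000363, 0.00168, 0.00168 and 0.00519 with an estimated correlation). The replication licensing genes CDC45 (3.50 ± 0.091), ORC1 (3.08 ± 0.079), CDC6 (3.30 ± 0.086) and MCM10 (2.65 ± 0.069) rose. So did ANLN, needed for cytokinesis (3.83 ± 0.074), cyclin A2 (CCNA2, 3.19 ± 0.073) and the mitotic kinesins KIF20A (2.97 ± 0.067) and KIF23 (2.93 ± 0.066). Among repair genes BLM, a helicase, rose by 3.40 ± 0.080, the nuclease gene EXO1 by 3.13 ± 0.073, FANCI by 2.50 ± 0.069 and BRCA2 by 2.24 ± 0.077, whereas FANCF, FAN1 and MUS81 fell (-0.75, -0.29 and -0.85). The keratin gene KRT15 fell by -7.50 ± 0.11. TP63, the master regulator of basal squamous cells, fell by -3.30 ± 0.10, the desmosome gene DSG3 by -3.14 ± 0.087 and KRT6A by -2.16 ± 0.079. Of 5 markers of columnar epithelium, 3 rose and 2 fell (camera, adjusted p = 0.00532; adjusted p = 0.0584 with an estimated correlation). The simple keratin genes KRT8 (2.27 ± 0.12) and KRT18 (2.18 ± 0.077) and the adhesion gene EPCAM (1.38 ± 0.063) rose and the mucin gene MUC1 (-1.72 ± 0.31) fell.

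Stress and interferon transcripts were lower in the same KYSE 150 knockout cells. Interferon-stimulated genes fell in 38 of 44 genes (40 adjusted over the list alone), median -1.65, and genes of the integrated stress response, which ATF4 drives, in 23 of 31 genes (23 adjusted over the list alone), median -1.11. Both lists passed with camera at the preset correlation (adjusted p = 1.54e-12 and 4.30e-13) but not otherwise (adjusted p = 0.0584 for each with an estimated correlation). The antiviral genes OAS1 (-3.86 ± 0.21), OASL (-3.67 ± 0.16), IFI44 (-2.62 ± 0.14) and PARP14 (-2.03 ± 0.097) fell, while OAS3 and USP18 rose (0.85 and 0.82). CHAC1, which degrades glutathione, fell by -3.21 ± 0.13. The mTORC1 inhibitor gene DDIT4 fell by -2.79 ± 0.081, PCK2 by -2.22 ± 0.086 and SESN2 by -2.14 ± 0.084. Heat shock chaperones rose in 15 of 20 genes (15 adjusted over the list alone). HSP90AA1 was at 3.11 ± 0.075, HSPA8 at 2.01 ± 0.095 and HSPB1 against them at -1.44. Cholesterol biosynthesis genes fell in 17 of 24 genes (17 adjusted over the list alone). SREBF2 stood at -1.48 ± 0.071 and TM7SF2 at -1.93 ± 0.096. These passed camera as well (adjusted p = 5.33e-07 and 0.000114; adjusted p = 0.0906 and 0.0584 with an estimated correlation). GDF15, a stress cytokine, fell from 45.9 ± 5.28 to 1.17 ± 0.631 CPM (-5.28 ± 0.23) and CDKN1A, the p53 target that halts the cycle, by -1.34 ± 0.074. MDM2 rose by 0.42 ± 0.077, CXCL8 by 2.69 ± 0.21 and ATF3 fell by -1.10 ± 0.11. LOXL4, a lysyl oxidase of the matrix, was at least 324-fold lower, the CTP synthase gene CTPS2 at least 119-fold, PALMD 106-fold, the tropomyosin gene TPM2 94.4-fold, the complement gene CFB 88.9-fold and ARSD 67.6-fold, each with 0 counts in the knockout. Whether these falls came with the loss of MAGEA6 or with another difference between the cells was not tested. The largest rises were in MARCHF4, a ubiquitin ligase (7.70 ± 0.45), CDK15 (5.94 ± 0.57), MYPN (5.93 ± 0.62), MYEOV (5.32 ± 0.26), NAV3 (5.19 ± 0.55) and the peptide hormone gene APLN (5.06 ± 0.28).

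Of 16801 genes tested in KYSE 150, edgeR called 5493 higher and 5388 lower in untreated MAGEA6-KO cells at adjusted p < 0.05, and 4766 of these 10881 changed at least 2-fold. With so many genes changed the zero of the scale rests on TMM, and upper-quartile factors moved the median fold change by -0.17. Of the 10958 genes called with those factors 40.8% were higher, against 50.5%.

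In untreated KYSE 510, MAGEA6-KO cells held more transcripts of endoplasmic reticulum stress and of NF-kB and cytokine genes than sgNC cells. Genes of the unfolded protein response rose in 19 of 25 genes (20 adjusted over the list alone), with a median of 0.47 (camera, adjusted p = 2.46e-39; adjusted p = 0.00271 with an estimated correlation). HSPA5, the main chaperone of the endoplasmic reticulum, rose from 543 ± 5.26 to 1818 ± 178 CPM (1.74 ± 0.061). HERPUD1, which acts in the removal of misfolded proteins, rose by 1.80 ± 0.068, the cochaperone gene SDF2L1 by 1.59 ± 0.16 and calreticulin (CALR) by 0.66 ± 0.052. Integrated stress response genes rose in 19 of 32 genes (21 adjusted over the list alone), median 0.27, led by DDIT3, a proapoptotic transcription factor (1.81 ± 0.11), SESN2 (1.03 ± 0.072), STC2 (0.80 ± 0.066) and the pseudokinase gene TRIB3 (0.78 ± 0.065). NF-kB and inflammatory cytokine genes rose in 12 of 29 genes (17 adjusted over the list alone), median 0.51, among them the adhesion gene ICAM1 (1.07 ± 0.085), the cytokine genes IL1A (1.01 ± 0.077) and IL1B (0.85 ± 0.090), and TNFAIP2 (0.67 ± 0.067). The camera test called both lists (adjusted p = 2.90e-22 and 1.62e-15; adjusted p = 0.00542 and 0.0406 with an estimated correlation). GDF15 rose from 64.1 ± 5.29 to 185 ± 15 CPM (1.53 ± 0.069), the opposite of its fall in KYSE 150.

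G2/M and mitosis genes were slightly lower in the KYSE 510 knockout, in 19 of 42 genes (27 adjusted over the list alone) with a median of -0.21, and CDC20 rose against them (0.15). DLGAP5, a spindle gene, changed by -0.36 ± 0.063, ASPM by -0.32 ± 0.057, the kinesin gene KIF11 by -0.35 ± 0.070 and topoisomerase TOP2A by -0.23 ± 0.046. Heat shock chaperones fell in 10 of 20 genes (10 adjusted over the list alone), median -0.17. HSPA8 was at -0.56 ± 0.044, HSPA1A at -0.83 ± 0.075, HSPA1B at -0.81 ± 0.072 and HSP90AA1 at -0.42 ± 0.048. Both falls passed camera (adjusted p = 7.60e-11 and 6.86e-10; adjusted p = 0.0345 and 0.0107 with an estimated correlation). The largest falls were in AUTS2, a regulator of transcription (-3.30 ± 0.37), AMOT, a Hippo pathway scaffold (-2.69 ± 0.20), the selenium carrier gene SELENOP (-2.19 ± 0.26), the glypican gene GPC4 (-1.95 ± 0.20), MAGEA3, and the deiodinase gene DIO2 (-1.77 ± 0.15). The largest rises were in LCP1, an actin bundling gene of leukocytes (1.98 ± 0.064), the ciliary regulator FOXJ1 (1.83 ± 0.35), DDIT3, HERPUD1, the stress hormone gene FGF21 (1.76 ± 0.21) and HSPA5. ATF3 rose by 0.61 ± 0.086 and CXCL8 by 0.70 ± 0.20, whereas CDKN1A (-0.0026 ± 0.069) and MDM2 (0.093 ± 0.065) did not pass. Of 16925 genes tested, edgeR called 1128 higher and 1144 lower at adjusted p < 0.05, and 220 of these 2272 changed at least 2-fold. The count depended on single libraries: it was 1339 without sgNC replicate 1, 1344 without sgNC replicate 2, 1321 without MAGEA6-KO replicate 1 and 1431 without MAGEA6-KO replicate 3.

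KYSE 150 cells with cisplatin alone held more transcripts of the cell cycle, repair, NF-kB, and BCL2 family and caspase lists than sgNC cells. They held fewer of basal keratinocyte, stress response and sterol genes. For cell cycle, repair and stress response genes this rests on the sgNC libraries, which stood apart from the 3 other groups. Within knockout cells the S phase and G2/M lists did not rise with cisplatin, and 4 of 32 (4 adjusted over the list alone) repair genes rose and 20 of 32 (21 adjusted over the list alone) fell (camera, adjusted p = 0.0747). The list of sterol (cholesterol biosynthesis) genes did not pass within knockout cells (camera, adjusted p = 0.105). Relative to sgNC, S phase genes rose in 40 of 44 genes (40 adjusted over the list alone), median 1.42, G2/M genes in 41 of 42 genes (41 adjusted over the list alone), median 1.53, and crosslink and homologous recombination repair genes in 26 of 32 genes (26 adjusted over the list alone), median 1.36. The camera test called all 3 (adjusted p = 6.66e-28, 7.97e-34 and 5.39e-13; adjusted p = 0.00676, 0.0126 and 0.00920 with an estimated correlation). ORC6 of the origin recognition complex rose by 3.11 ± 0.11, MCM10 by 2.88 ± 0.069, the phosphatase gene CDC25A by 2.86 ± 0.090. CDC20 rose by 2.71 ± 0.081, the checkpoint gene MAD2L1 by 2.49 ± 0.068. XRCC2, a recombination gene, rose by 2.76 ± 0.097, EXO1 by 2.63 ± 0.072 and BLM by 2.55 ± 0.079, while FANCC and FANCF fell (-1.23 and -0.97). NF-kB and cytokine genes rose in 21 of 29 genes (21 adjusted over the list alone), median 1.61. The apoptosis inhibitor gene BIRC3 stood at 4.09 ± 0.094, IL11 at 2.71 ± 0.10, LIF at 2.57 ± 0.089 and NFKB2 at 2.50 ± 0.076. BCL2 family and caspase genes rose in 21 of 32 genes (23 adjusted over the list alone), median 0.49, with BCL2 itself against them (-0.80). Both apoptosis inhibitor genes, BIRC3 and BIRC5 (1.76 ± 0.082), and promoters of cell death, PMAIP1 (2.15 ± 0.098) and TNFRSF10A (1.09 ± 0.076), rose. The NF-kB and BCL2 lists passed camera too (adjusted p = 1.72e-09 and 0.000299, and adjusted p = 0.0148 and 0.0157 with an estimated correlation). Within knockout cells 14 of 32 (15 adjusted over the list alone) BCL2 family and caspase genes rose with cisplatin and 12 of 32 (12 adjusted over the list alone) fell, median 0.15.

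Basal keratinocyte genes fell under cisplatin in 22 of 25 genes (22 adjusted over the list alone) in KYSE 150, median -2.27. KRT15 was at -7.21 ± 0.11, KRT5 at -3.91 ± 0.097, KRT6A at -3.43 ± 0.084 and the integrin gene ITGA3 at -2.70 ± 0.072, whereas KRT14, the partner of KRT5, rose from 31.6 ± 4.73 to 126 ± 6.75 CPM (1.99 ± 0.11). Within knockout cells KRT15 changed by -0.56 ± 0.10 with cisplatin. Integrated stress response genes fell in 26 of 31 genes (26 adjusted over the list alone), median -1.27, but within knockout cells 11 of 31 (11 adjusted over the list alone) rose and 13 of 31 (13 adjusted over the list alone) fell (camera, adjusted p = 0.659). The cystine transporter gene SLC7A11 stood at -3.95 ± 0.14, DDIT4 at -3.50 ± 0.084, the amino acid transporter gene SLC7A5 at -3.16 ± 0.069 and TRIB3 at -1.61 ± 0.073. Cholesterol genes fell in 21 of 24 genes (21 adjusted over the list alone), median -0.81. Within knockout cells 13 of 24 (13 adjusted over the list alone) fell with cisplatin and 3 of 24 (3 adjusted over the list alone) rose, median -0.35 (camera, adjusted p = 0.105; adjusted p = 0.334 with an estimated correlation). Against sgNC the 3 lists passed camera (adjusted p = 3.70e-23, 3.47e-13 and 5.41e-06; adjusted p = 0.00676, 0.0493 and 0.0267 with an estimated correlation). The interferon-stimulated genes ISG15 (5.44 ± 0.14), IFIT2 (4.48 ± 0.13), IFIT1 (4.02 ± 0.12) and SAMD9 (2.43 ± 0.076) rose strongly. Their list rose in 23 of 44 genes (23 adjusted over the list alone), median 0.35 (camera, adjusted p = 1.47e-07; adjusted p = 0.172 with an estimated correlation). Immediate early genes rose in 22 of 31 genes (22 adjusted over the list alone), with NR4A1 at 4.88 ± 0.13. Ribosomal protein genes fell in 44 of 51 genes (45 adjusted over the list alone), with RPL3 at -2.30 ± 0.090 (camera, adjusted p = 3.44e-06 and 3.48e-05; adjusted p = 0.198 and 0.559 with an estimated correlation). Of the p53 targets, AEN (2.46 ± 0.096), PMAIP1 (2.15 ± 0.098), CDKN1A (1.13 ± 0.071), CCNG1 (1.02 ± 0.056) and MDM2 (0.71 ± 0.077) rose, yet the list as a whole split, with 16 of 38 (16 adjusted over the list alone) higher and 15 of 38 (15 adjusted over the list alone) lower (camera, adjusted p = 0.212). CXCL8 rose by 2.44 ± 0.21 and ATF3 by 0.64 ± 0.11, and GDF15 fell by -0.47 ± 0.18.

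The gastrin gene GAST was at least 92.0-fold higher with cisplatin in KYSE 150, the sodium channel gene SCN3A at least 78.4-fold and the chemokine gene CCL3L3 at least 74.4-fold. RTL9 rose by 8.78 ± 0.66 and CCL3 by 8.22 ± 0.75. BBOX1 of carnitine synthesis was at least 310-fold lower, the kinase gene MAP2K6 231-fold, NELL2 172-fold and PAPPA2 67.7-fold. The anchoring protein gene AKAP6 (-8.15 ± 0.57) and complement C5 (-8.12 ± 0.54) fell. With cisplatin, MAGEA6 (0.66 ± 0.078), MAGEA3 (0.60 ± 0.083), MAGEA2 (1.39 ± 0.088) and MAGEA12 (1.00 ± 0.073) rose and MAGEA4 fell (-0.39 ± 0.066). Of 16801 genes edgeR called 5789 higher and 5626 lower, and 5381 of these 11415 changed at least 2-fold.

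In KYSE 510 cisplatin alone also raised S phase and repair transcripts and lowered basal keratinocyte genes. S phase genes rose in 44 of 44 genes (44 adjusted over the list alone), median 1.53, and crosslink and homologous recombination repair genes in 24 of 32 genes (26 adjusted over the list alone), median 0.76 (camera, adjusted p = 1.06e-35 and 3.29e-07; adjusted p = 0.00426 and 0.00426 with an estimated correlation). CDC25A rose by 3.05 ± 0.070, CDC6 by 2.49 ± 0.070, the flap nuclease gene FEN1 by 2.54 ± 0.066, RRM2, a ribonucleotide reductase subunit, by 2.54 ± 0.060. EXO1 rose by 2.83 ± 0.065, XRCC2 by 1.96 ± 0.074, UBE2T of the Fanconi pathway by 1.80 ± 0.074 and BLM by 1.36 ± 0.058, while FANCC and SLX4 fell (-1.40 and -0.89). G2/M genes moved both ways, 14 of 42 (14 adjusted over the list alone) up and 21 of 42 (22 adjusted over the list alone) down, with AURKB at 1.04 ± 0.063, CENPE at -1.16 ± 0.069, HMMR at -1.07 ± 0.067 and TOP2A at -0.71 ± 0.046, and the list did not pass (camera, adjusted p = 0.364). Immediate early and MAPK feedback genes rose in 25 of 34 genes (25 adjusted over the list alone), median 1.61. The phosphatase gene DUSP1 stood at 4.05 ± 0.11, the nuclear receptor gene NR4A1 at 3.95 ± 0.099, FOSL1 at 3.32 ± 0.11 and ETV5 at 2.71 ± 0.10, whereas FOS and EGR1 fell (-0.74 and -0.74). Basal keratinocyte genes fell in 19 of 25 genes (19 adjusted over the list alone), median -1.26. KRT15 was at -6.48 ± 0.084, NGFR at -2.01 ± 0.064, ITGA6 at -1.49 ± 0.054 and KRT5 at -1.30 ± 0.046, against rises of KRT6A and KRT6B (1.84 and 2.57). The camera test called both lists (adjusted p = 1.47e-11 and 3.90e-10; adjusted p = 0.0496 and 0.0496 with an estimated correlation).

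NRF2 target genes fell in 27 of 28 genes (27 adjusted over the list alone) in KYSE 510 with cisplatin, median -0.90. CYP4F11 stood at -2.17 ± 0.077, the transketolase gene TKT at -1.84 ± 0.052, GCLC of glutathione synthesis at -1.41 ± 0.060 and the efflux pump gene ABCC2 at -1.35 ± 0.057. Hypoxia response genes fell in 26 of 29 genes (26 adjusted over the list alone), median -0.98. NDRG1 was at -3.15 ± 0.10, LOXL2 at -2.35 ± 0.081, the glucose transporter gene SLC2A1 at -2.03 ± 0.065 and BHLHE40 at -1.07 ± 0.054. Both passed camera only at the preset correlation (adjusted p = 7.44e-11 and 6.80e-08; adjusted p = 0.0879 and 0.140 with an estimated correlation). IL1RL1, the receptor of interleukin 33, was at least 680-fold higher, IL6 rose by 7.18 ± 0.44, IL7R by 5.06 ± 0.11, SHISA2 by 4.97 ± 0.34, INHBA by 4.85 ± 0.24 and the readthrough locus BIVM-ERCC5 by 9.0 ± 2.8. CHURC1-FNTB was at least 102-fold lower, the crystallin gene CRYL1 86.8-fold, HHAT 83.1-fold and the formin gene FHOD3 79.9-fold. SDK1 (-9.06 ± 0.40) and CHODL (-8.16 ± 0.66) fell. CDKN1A rose by 1.10 ± 0.069, GDF15 by 0.87 ± 0.068, MDM2 by 0.32 ± 0.064, CXCL8 by 2.78 ± 0.20, ATF3 by 1.91 ± 0.086, MAGEA6 by 1.39 ± 0.30 and MAGEA3 by 1.16 ± 0.092. The edgeR test called 5696 of 16925 genes higher and 5832 lower, and 5063 of these 11528 changed at least 2-fold.

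Long genes fell under cisplatin in both lines. In KYSE 150 the median change against sgNC went from 0.29 in the fifth of genes with the shortest genomic span to -0.79 in the fifth with the longest, and in KYSE 510 from 0.39 to -0.80. Within knockout cells the same medians were 0.34 and -0.92 in KYSE 150 and 0.41 and -0.88 in KYSE 510. The knockout alone moved these medians less, 0.16 and -0.17 in KYSE 150 and 0.017 and -0.034 in KYSE 510.

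**Figure D2:**
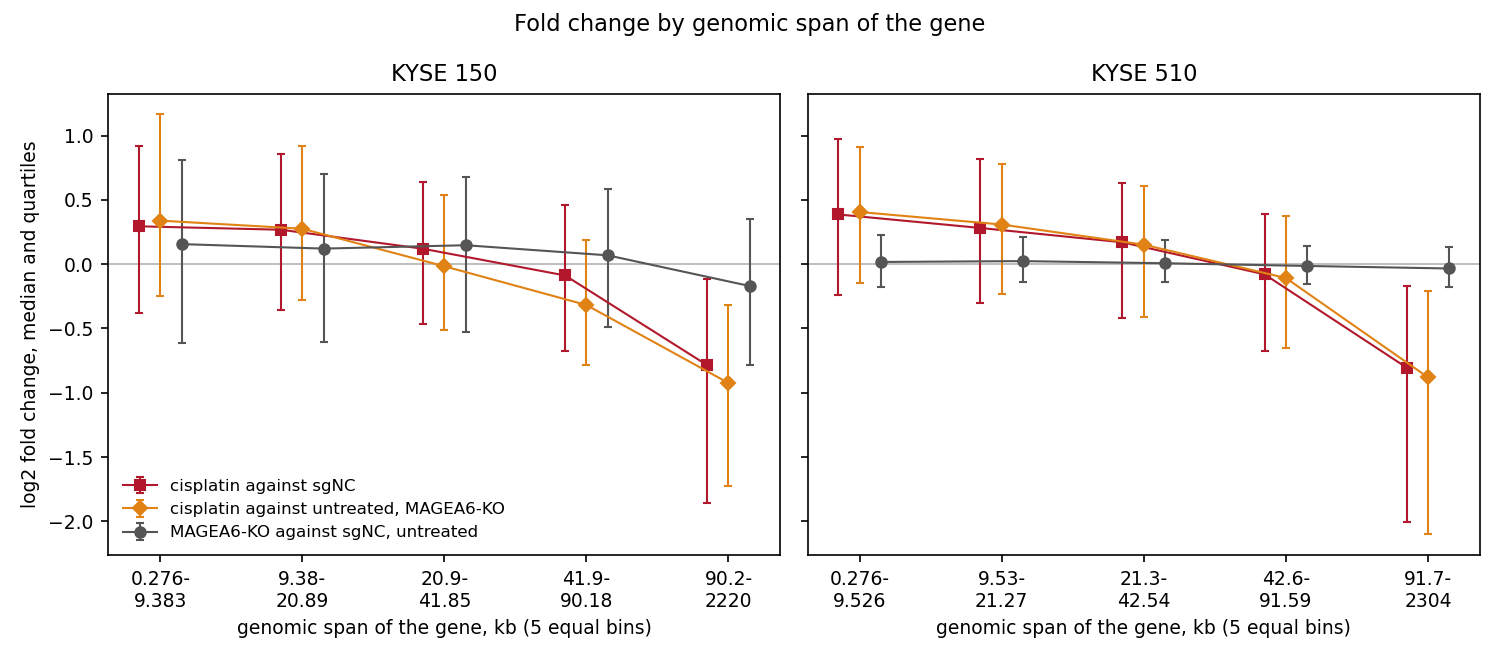
Median log2 fold change of genes in 5 bins of genomic span, with quartiles, for 3 comparisons in each cell line.

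Under cisplatin, KYSE 150 MAGEA6-KO cells held fewer interferon-stimulated and basal keratinocyte transcripts and more ribosomal protein and histone transcripts than cells given cisplatin alone. Interferon-stimulated genes were lower in 31 of 44 genes (32 adjusted over the list alone), median -0.76. IFIT2 stood at -2.50 ± 0.12, IFIT3 at -2.25 ± 0.15, ISG15 at -2.20 ± 0.12 and SAMD9 at -1.44 ± 0.074. Basal genes were lower in 16 of 25 genes (16 adjusted over the list alone), median -0.53, with KRT14 falling from 126 ± 6.75 to 2.32 ± 0.331 CPM (-5.76 ± 0.14), KRT17 at -2.29 ± 0.085, TP63 at -1.94 ± 0.097 and SOX2 against them at 2.22. Ribosomal protein genes were higher in 48 of 51 genes (48 adjusted over the list alone), median 0.80. RPS12 was at 1.40 ± 0.13 and RPLP1 at 1.33 ± 0.10. Replication-dependent histone genes were higher in 19 of 22 genes (19 adjusted over the list alone), median 1.19. H4C8 stood at 1.69 ± 0.11 and H2BC21 at 1.57 ± 0.13. Genes of the unfolded protein response were higher in 17 of 25 genes (17 adjusted over the list alone), median 0.53. CRELD2 was at 1.41 ± 0.13, calnexin (CANX) at 1.07 ± 0.076 and HSP90B1 at 0.75 ± 0.059. These 5 lists passed camera only at the preset correlation (adjusted p = 1.37e-13, 1.75e-09, 2.73e-12, 1.07e-07 and 0.000179; adjusted p = 0.0930, 0.0930, 0.439, 0.0930 and 0.0930 with an estimated correlation). G2/M genes were higher in 19 of 42 genes (21 adjusted over the list alone), with a median of only 0.17, and S phase genes in 23 of 44 genes (24 adjusted over the list alone) (camera, adjusted p = 6.19e-05 and 0.0252; adjusted p = 0.439 for each with an estimated correlation). HMMR stood at 1.82 ± 0.082, E2F1 at 1.55 ± 0.083 and MCM10 against them at -1.06 ± 0.064. NRF2 targets were higher in 17 of 28 genes (18 adjusted over the list alone), with OSGIN1 at 1.75 ± 0.14 and NQO1 at 0.82 ± 0.094 (camera, adjusted p = 0.000287; adjusted p = 0.192 with an estimated correlation).

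CTPS2 was at least 77.3-fold lower in KYSE 150 knockout cells with cisplatin than with cisplatin alone, and TPM2 (-8.66 ± 0.46), CMTM3 (-7.06 ± 0.38), the gastrin releasing peptide receptor gene GRPR (-6.61 ± 0.59) and the basement membrane collagen genes COL4A2 (-5.98 ± 0.39) and COL4A1 (-5.92 ± 0.43) were lower. The MHC class II genes HLA-DQB1 (6.53 ± 0.68) and HLA-DRB1 (4.84 ± 0.81), the iron-binding lipocalin gene LCN2 (4.55 ± 0.18), RNF225 (3.96 ± 0.43), COMMD10 (3.94 ± 0.35) and the folate enzyme gene ALDH1L1 (3.77 ± 0.34) were higher. GDF15 differed by -1.65 ± 0.18, CXCL8 by 1.65 ± 0.18 and MDM2 by -0.30 ± 0.076, while CDKN1A (-0.17 ± 0.070) and ATF3 (0.25 ± 0.11) did not pass. The edgeR test called 4225 of 16801 genes higher and 4130 lower, and 2134 of these 8355 differed at least 2-fold. One library, MAGEA6-KO with cisplatin replicate 3, held relatively more short transcripts, and without it the median of the ribosomal list was 0.58.

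Under cisplatin, KYSE 510 MAGEA6-KO cells held slightly fewer S phase and repair transcripts than cells given cisplatin alone. S phase genes were lower in 31 of 44 genes (33 adjusted over the list alone), median -0.28. PRIM1 of the primase was at -0.77 ± 0.066, POLA1 at -0.77 ± 0.083, RRM2 at -0.72 ± 0.057 and MCM5 at -0.58 ± 0.060. Crosslink and homologous recombination repair genes were lower in 13 of 32 genes (14 adjusted over the list alone), median -0.20. BRIP1 stood at -0.63 ± 0.088, RBBP8 at -0.62 ± 0.063, RAD51AP1 at -0.56 ± 0.099 and FANCI at -0.26 ± 0.045. Both passed camera (adjusted p = 1.07e-17 and 0.000871; adjusted p = 0.0389 and 0.0444 with an estimated correlation). NF-kB and cytokine genes were higher in 12 of 29 genes (15 adjusted over the list alone), with TNFAIP2 at 0.64 ± 0.067 and BIRC3 at 0.60 ± 0.072 (camera, adjusted p = 4.16e-05; adjusted p = 0.280 with an estimated correlation). AUTS2 (-4.69 ± 0.43), SENP3-EIF4A1 (-2.98 ± 0.74), TXNIP, an inhibitor of thioredoxin (-2.19 ± 0.097), the smooth muscle actin gene ACTG2 (-2.15 ± 0.38), CFAP44 (-2.08 ± 0.21) and MAGEA6 fell the most. The acute phase genes SERPINA3 (4.22 ± 0.66) and SAA1 (1.61 ± 0.22), ADAMTSL4 (1.88 ± 0.15), SH2D3C (1.80 ± 0.24), PDZK1IP1 (1.57 ± 0.15) and ALDH1L1 (1.48 ± 0.14) rose the most. ATF3 was higher (0.38 ± 0.081) and CDKN1A lower (-0.32 ± 0.067), and GDF15 (0.096 ± 0.067), MDM2 (0.023 ± 0.064) and CXCL8 (0.31 ± 0.18) did not pass. The edgeR test called 1958 of 16925 genes higher and 2135 lower, and 439 of these 4093 differed at least 2-fold.

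Within KYSE 150 MAGEA6-KO cells, cisplatin raised interferon-stimulated, NF-kB and histone genes and lowered S phase and basal keratinocyte genes. Interferon-stimulated genes rose in 36 of 44 genes (36 adjusted over the list alone), median 2.13. OASL was at 5.42 ± 0.17, IFI44 at 4.76 ± 0.14, IFIT2 at 3.96 ± 0.13 and ISG15 at 3.86 ± 0.13. NF-kB and cytokine genes rose in 21 of 29 genes (21 adjusted over the list alone), median 1.28. BIRC3 stood at 2.01 ± 0.084, ZC3H12A at 1.93 ± 0.11, RELB at 1.73 ± 0.10 and NFKB2 at 1.35 ± 0.074. Histone genes rose in 20 of 22 genes (21 adjusted over the list alone), median 1.68. H3C10 was at 2.45 ± 0.15 and H2BC21 at 2.02 ± 0.13. S phase genes fell in 30 of 44 genes (30 adjusted over the list alone), median -0.60. POLA1 stood at -2.17 ± 0.085, GINS1 at -1.64 ± 0.085 and UHRF1 at -1.59 ± 0.099. G2/M genes fell in 32 of 42 genes (32 adjusted over the list alone), median -0.34. ANLN was at -2.08 ± 0.069. Basal genes fell in 19 of 25 genes (19 adjusted over the list alone), median -0.83. KRT6A stood at -2.40 ± 0.087, ITGA6 at -2.19 ± 0.083 and SOX2 against them at 2.69. None of these passed camera beyond the preset correlation (adjusted p = 4.07e-17, 1.48e-05, 1.48e-05, 0.000586, 0.00423 and 7.79e-06; adjusted p = 0.152, 0.152, 0.152, 0.197, 0.400 and 0.152 with an estimated correlation). Among p53 targets 16 of 38 (16 adjusted over the list alone) rose and 11 of 38 (11 adjusted over the list alone) fell, median 0.17 (camera, adjusted p = 0.0264; adjusted p = 0.252 with an estimated correlation). PMAIP1 (3.62 ± 0.10), BBC3 (2.50 ± 0.12) and CDKN1A (2.30 ± 0.075) rose. So did GDF15 (3.15 ± 0.23), ATF3 (1.99 ± 0.11), CXCL8 (1.40 ± 0.18), MAGEA6 (2.43 ± 0.085) and MAGEA3 (2.23 ± 0.089), and MDM2 did not pass (-0.0075 ± 0.076).

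Among the largest rises with cisplatin in KYSE 150 knockout cells were HERC5, which attaches ISG15 to proteins (8.47 ± 0.45), the RNA sensor gene DHX58 (8.27 ± 0.41), the guanylate binding gene GBP5 (6.91 ± 0.63), BIVM-ERCC5 (6.79 ± 1.70) and SCN3A (6.09 ± 0.52). The largest falls were in the receptor kinase gene ROR1 (-6.79 ± 0.42), the WNT ligand gene WNT5B (-5.07 ± 0.31), TMEM117 (-5.36 ± 0.44), the kinase gene PRKCA (-4.80 ± 0.17), ARHGEF26 (-4.80 ± 0.48) and ARL15 (-4.75 ± 0.31). In all 5566 of 16801 genes were higher and 5831 lower by edgeR, and 5324 of these 11397 changed at least 2-fold.

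Within KYSE 510 MAGEA6-KO cells, cisplatin raised S phase, repair, immediate early and heat shock genes and lowered basal keratinocyte genes. S phase genes rose in 42 of 44 genes (42 adjusted over the list alone), median 1.37. CDC25A was at 2.93 ± 0.070, RRM2 at 2.28 ± 0.060, FEN1 at 2.23 ± 0.066 and MCM4 at 1.49 ± 0.044. Repair genes rose in 23 of 32 genes (24 adjusted over the list alone), median 0.60. EXO1 stood at 2.86 ± 0.066, RAD54L at 1.90 ± 0.082 and XRCC2 at 1.77 ± 0.074. Immediate early genes rose in 28 of 34 genes (28 adjusted over the list alone), median 1.202. NR4A1 was at 4.55 ± 0.099 and DUSP1 at 3.42 ± 0.10. Heat shock chaperones rose in 15 of 20 genes (15 adjusted over the list alone), median 0.82. CHORDC1 stood at 1.59 ± 0.063, HSPH1 at 1.57 ± 0.053 and FKBP4 at 1.46 ± 0.048. Basal genes fell in 19 of 25 genes (19 adjusted over the list alone), median -1.37. KRT15 was at -5.45 ± 0.079 and NGFR at -1.91 ± 0.062. The camera test called all 5 lists (adjusted p = 3.29e-31, 2.06e-06, 3.11e-12, 5.80e-07 and 2.35e-13; adjusted p = 0.00315, 0.00704, 0.0186, 0.0186 and 0.0186 with an estimated correlation). Unfolded protein response genes fell in 19 of 25 genes (19 adjusted over the list alone), median -0.67, with HSPA5 at -2.49 ± 0.062, HERPUD1 at -2.31 ± 0.069 and ATF6 at -1.96 ± 0.080 (camera, adjusted p = 3.46e-08; adjusted p = 0.0640 with an estimated correlation). IL6 (8.94 ± 0.53), IL1RL1 (7.08 ± 0.24), the cell cycle regulator RGCC (4.56 ± 0.50), SHISA2 (4.39 ± 0.32) and TLR4 (4.13 ± 0.31) rose the most. AKAP6 was at least 165-fold lower, followed by RBMS3 (-8.36 ± 0.62), PLXDC2 (-7.60 ± 0.40), PRKCA (-7.51 ± 0.32), NEBL (-7.03 ± 0.23) and PARD3B (-6.95 ± 0.49). CDKN1A (0.78 ± 0.069), MDM2 (0.25 ± 0.064), CXCL8 (2.39 ± 0.19), ATF3 (1.67 ± 0.084) and MAGEA3 (1.36 ± 0.097) rose, GDF15 fell (-0.57 ± 0.067) and MAGEA6 did not pass (0.73 ± 0.32). In edgeR 5729 of 16925 genes were higher and 5680 lower, and 4771 of these 11409 changed at least 2-fold.

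**Figure D3:**
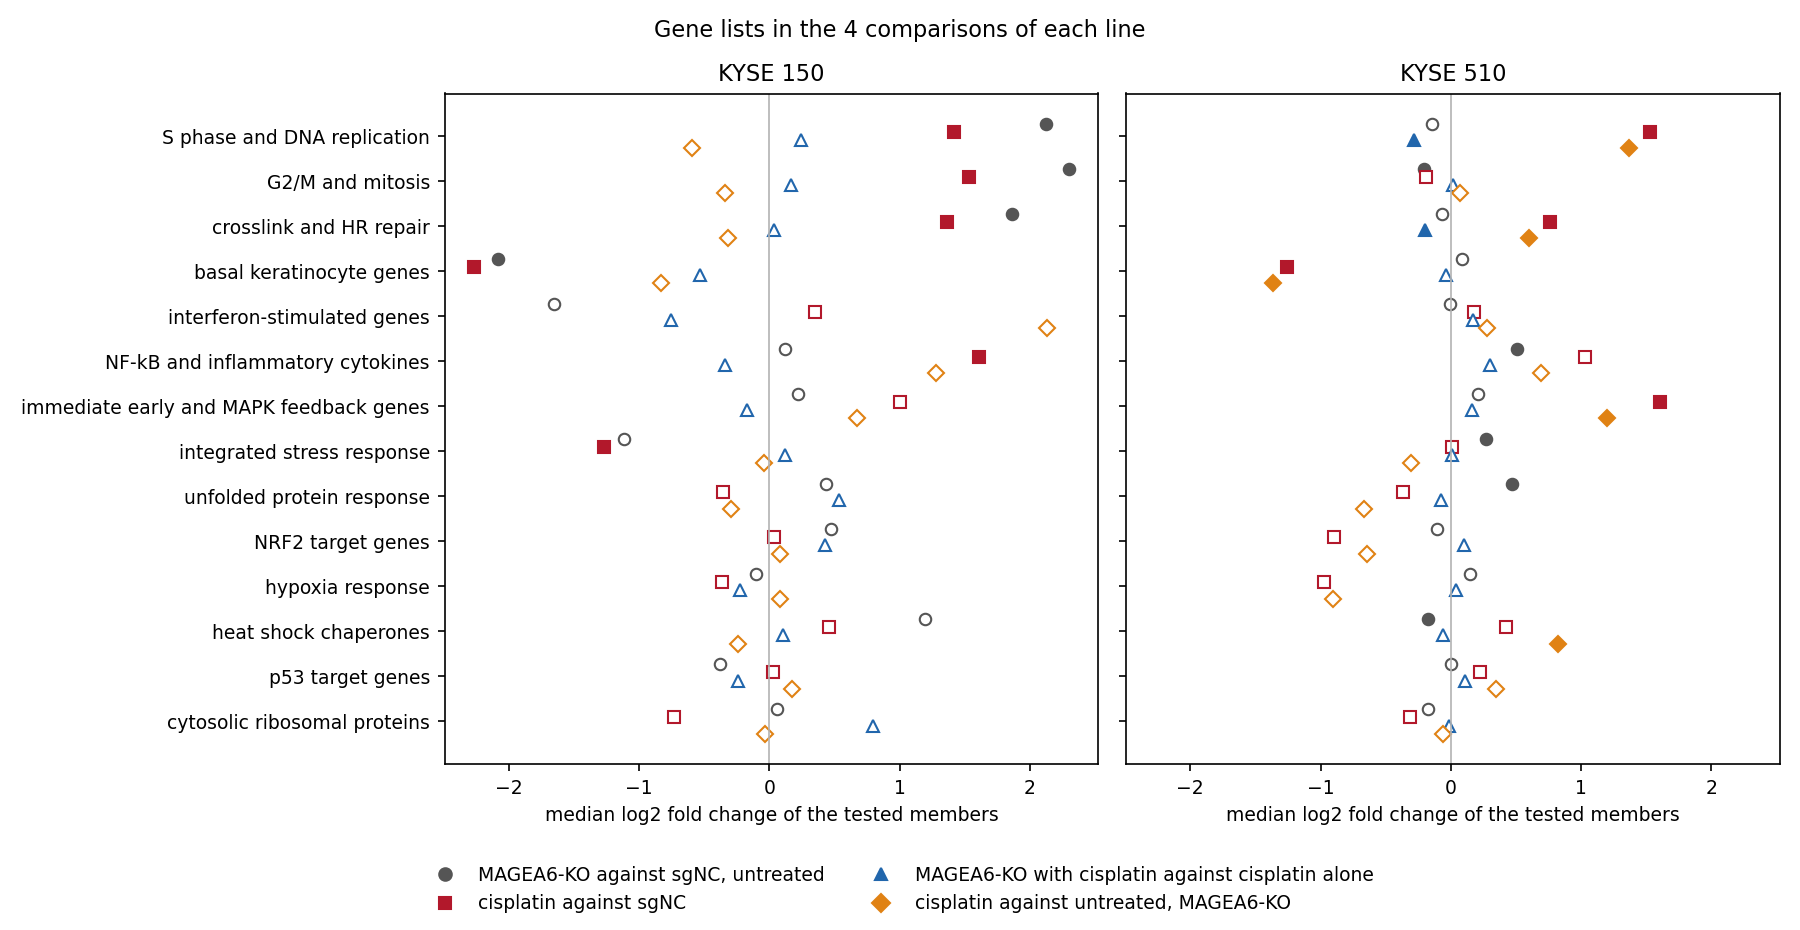
Median log2 fold change of 14 gene lists in the 4 comparisons of groups in each cell line. Filled points mark lists that passed camera at the preset correlation and with an estimated correlation.

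In KYSE 150 the effect of cisplatin on the cell cycle depended on MAGEA6-KO: it was a rise against sgNC cells and a slight fall within knockout cells. The interaction, the cisplatin effect in knockout cells minus that against sgNC, was negative for S phase genes in 43 of 44 genes (43 adjusted over the list alone), median -1.92, for G2/M genes in 41 of 42 genes (41 adjusted over the list alone), median -1.96, and for crosslink and homologous recombination repair genes in 26 of 32 genes (26 adjusted over the list alone), median -1.70. Basal keratinocyte genes had a positive interaction in 19 of 25 genes (19 adjusted over the list alone), median 1.03, and integrated stress response genes in 23 of 31 genes (23 adjusted over the list alone), median 1.15. The camera test called all 5 (adjusted p = 1.53e-57, 4.68e-62, 4.82e-24, 2.53e-10 and 9.78e-18; adjusted p = 0.000366, 0.00247, 0.00128, 0.0412 and 0.0412 with an estimated correlation). MCM10 (-3.71 ± 0.094), CDC45 (-3.45 ± 0.12), ANLN (-3.67 ± 0.097), CDK1 (-2.49 ± 0.088), BLM (-3.36 ± 0.11) and EXO1 (-2.82 ± 0.096) had negative interactions. KRT15 (6.65 ± 0.14), DSG3 (2.69 ± 0.12), DDIT4 (3.06 ± 0.11), PCK2 (2.93 ± 0.12) and ASNS, which makes asparagine (2.34 ± 0.12), had positive ones, and KRT14 went against its list (-2.43 ± 0.19). By fitted size APOL4, BBOX1, CFB and LOXL4 led the positive interactions, each with 0 counts in 1 group, so no size is given. On the negative side the largest were in GRPR (-9.60 ± 0.81), MARCHF4 (-9.35 ± 0.54), MYEOV (-8.23 ± 0.30) and IL7R (-6.21 ± 0.20). MAGEA6 (1.77 ± 0.11), MAGEA3 (1.63 ± 0.12), GDF15 (3.62 ± 0.29), ATF3 (1.35 ± 0.15) and CDKN1A (1.17 ± 0.10) had positive interactions. CXCL8 (-1.04 ± 0.27) and MDM2 (-0.72 ± 0.11) had negative ones. Of 16801 genes edgeR called 4245 positive and 4753 negative interactions. Which sign was more frequent depended on scaling: with upper-quartile factors most called interactions were positive. A low cell cycle in the sgNC libraries alone would give a negative interaction of cell cycle genes too. Likewise, high stress response and basal keratinocyte transcripts in those libraries alone would give positive interactions of these 2 lists.

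In KYSE 510 the interaction lay in endoplasmic reticulum stress: the rise of these genes in the knockout was absent with cisplatin. Unfolded protein response genes had a negative interaction in 19 of 25 genes (20 adjusted over the list alone), median -0.53. HSPA5 stood at -1.87 ± 0.084, SDF2L1 at -1.98 ± 0.22, HERPUD1 at -1.67 ± 0.095 and CALR at -0.85 ± 0.074. Integrated stress response genes had one in 17 of 32 genes (19 adjusted over the list alone), median -0.33. DDIT3 was at -1.77 ± 0.15, TRIB3 at -1.19 ± 0.093 and ATF4 against them at 0.36. Both passed camera (adjusted p = 1.37e-31 and 2.37e-11; adjusted p = 0.00599 and 0.0433 with an estimated correlation). HSPA5 held 543 ± 5.26 CPM in sgNC cells, 354 ± 11.3 with cisplatin, 1818 ± 178 in the knockout and 325 ± 5.83 with both. DDIT3 held 14.2 ± 1.58, 27.9 ± 3.32, 49.8 ± 4.90 and 28.7 ± 1.69 CPM in the same order. A stress state of the untreated knockout cultures alone would give a negative interaction of these genes too, and it cannot be told from an effect of the knockout. Cholesterol biosynthesis genes had a positive interaction in 12 of 24 genes (13 adjusted over the list alone), with HMGCS1 at 1.07 ± 0.088 (camera, adjusted p = 1.11e-09; adjusted p = 0.0509 with an estimated correlation). By fitted size HHAT, CRYL1, SDK1 (3.32 ± 0.67) and SERPINA3 (3.07 ± 0.84) led the positive interactions. IL1RL1, AKAP6, the hair keratin gene KRT75 (-3.06 ± 0.29) and GPC4 (-2.78 ± 0.38) led the negative ones. No size is given for HHAT, CRYL1, IL1RL1 and AKAP6, which had 0 counts in 1 group. GDF15 (-1.43 ± 0.096) and CDKN1A (-0.32 ± 0.096) had negative interactions. MAGEA6 (-0.65 ± 0.44), MAGEA3 (0.20 ± 0.13), ATF3 (-0.24 ± 0.12), MDM2 (-0.071 ± 0.091) and CXCL8 (-0.40 ± 0.26) did not pass. Of 16925 genes edgeR called 1031 positive and 1154 negative interactions.

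**Figure D4:**
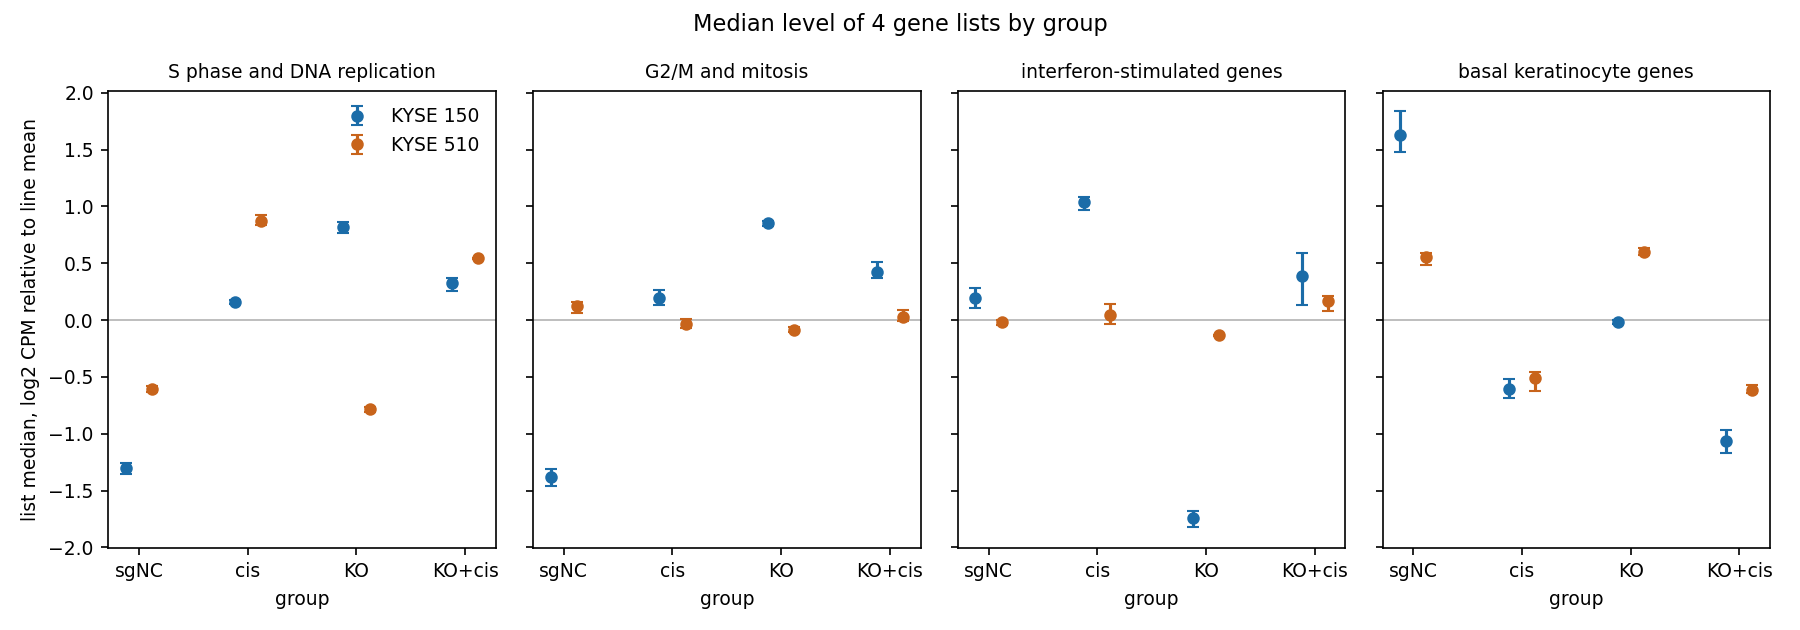
Median log2 level of 4 gene lists by group, relative to the mean of each cell line. Points are means of 3 libraries and bars run from the lowest to the highest library.

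The difference of MAGEA6-KO from sgNC differed between the lines above all in the cell cycle, higher in KYSE 150 than in KYSE 510. It rests on the same KYSE 150 sgNC libraries, whose state cannot be told from an effect of the knockout. The difference was positive for G2/M genes in 41 of 42 genes (41 adjusted over the list alone), median 2.44, S phase genes in 44 of 44 genes (44 adjusted over the list alone), median 2.14, repair genes in 26 of 32 genes (26 adjusted over the list alone), median 1.73, and heat shock chaperones in 14 of 20 genes (14 adjusted over the list alone), median 1.21. It was negative for basal keratinocyte genes in 23 of 25 genes (23 adjusted over the list alone), median -1.98, integrated stress response genes in 26 of 32 genes (26 adjusted over the list alone), median -1.54, interferon-stimulated genes in 36 of 46 genes (37 adjusted over the list alone), median -1.73, and hypoxia response genes in 15 of 30 genes (15 adjusted over the list alone), median -0.31. All 8 passed camera (adjusted p = 1.41e-93, 1.17e-72, 6.03e-24, 1.20e-12, 1.38e-29, 1.71e-25, 1.70e-12 and 4.96e-06), and also with the correlation estimated (adjusted p = 1.92e-06, 9.19e-08, 6.92e-06, 0.00276, 5.55e-05, 0.00210, 0.00855 and 0.0256 with an estimated correlation). ANLN (4.04 ± 0.093), RRM2 (4.15 ± 0.11), BLM (3.68 ± 0.097) and HSP90AA1 (3.46 ± 0.084) were among the genes more raised in KYSE 150. KRT15 (-7.34 ± 0.12), GDF15 (-6.87 ± 0.21), NUPR1 (-7.78 ± 0.29), OASL (-4.44 ± 0.27), HERPUD1 (-3.66 ± 0.10) and NDRG1 (-4.33 ± 0.14) were among those more lowered. By fitted size EVI2B, PRKAA2, PTPRQ and PWWP3B led the positive side and APOL4, LOXL4, ARSD and CFB the negative side. Each had 0 counts in a group or too few counts to be tested in 1 of the lines, so no size is given. MAGEA6 fell more in KYSE 150 (-1.25 ± 0.27), as did MAGEA3 (-0.75 ± 0.13). Of 18575 genes in the fit of all 24 libraries edgeR called 4441 positive and 5005 negative differences.

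The cisplatin effect against sgNC differed less between the lines, and most in mitotic genes. It rests on the same KYSE 150 sgNC libraries, which stood apart from the other groups of the line. Within KYSE 150 knockout cells, without sgNC, G2/M genes fell with cisplatin in 32 of 42 genes (32 adjusted over the list alone), median -0.34. The difference was positive for G2/M genes in 42 of 42 genes (42 adjusted over the list alone), median 1.755, and for repair genes in 20 of 32 genes (20 adjusted over the list alone), median 0.62, and negative for integrated stress response genes in 27 of 32 genes (27 adjusted over the list alone), median -1.21, and basal keratinocyte genes in 18 of 25 genes (18 adjusted over the list alone), median -0.90 (camera, adjusted p = 2.68e-78, 7.06e-05, 1.57e-25 and 1.97e-12; adjusted p = 1.64e-05, 0.0335, 0.00386 and 0.00771 with an estimated correlation). KIF20A (2.95 ± 0.078), BUB1 (2.88 ± 0.079), FANCD2 (1.96 ± 0.12), BIRC3 (3.81 ± 0.12) and IFIT1 (3.38 ± 0.18) were more raised in KYSE 150. KRT6A (-5.25 ± 0.13), DSC3 (-3.08 ± 0.14), SLC7A11 (-2.50 ± 0.15) and SESN2 (-1.94 ± 0.10) were more lowered. By fitted size RTL9, CHURC1-FNTB, COL5A1 and MOXD1 had the largest positive differences, and ADGRL3, APOL4, the collagenase gene MMP1 (-9.20 ± 0.79) and FAAH the largest negative ones. Except for MMP1, each had 0 counts in a group or too few counts to be tested in 1 of the lines, so no size is given. Of 18575 genes edgeR called 4071 positive and 4192 negative differences. Line, dose and a state of the KYSE 150 sgNC libraries could not be separated in this comparison.

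Across genes, the cisplatin effects correlated with each other at higher values than the knockout effects did, least so within the knockout between the lines. The fold changes of cisplatin against sgNC and within knockout cells correlated at r = 0.83 in KYSE 510 (16925 genes) and 0.53 in KYSE 150 (16801 genes), and between the lines the cisplatin effects against sgNC correlated at 0.61 (15296 genes). Those within knockout cells correlated at 0.32 between the lines, and 2525 genes changed in opposite directions where 3679.4 were expected. In KYSE 510, 4821 genes rose and 4727 fell in both cisplatin comparisons, where 1928.1 and 1957.2 were expected by chance, and 157 changed in opposite directions. In KYSE 150 the numbers were 3221 and 3527, with 1917.8 and 1952.6 expected, and 1825 opposite. The knockout effects without and with cisplatin correlated at 0.27 in KYSE 150 and 0.19 in KYSE 510. Between the lines the untreated knockout effects correlated at -0.052, and 993 genes changed in opposite directions where 722.42 were expected. NR4A1 rose with cisplatin in both lines, against sgNC and within the knockout, whereas GDF15 and HERPUD1 went in opposite directions with the knockout.

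The authors deposited DESeq2 results for the 4 cisplatin comparisons with limits of p 0.05 and 2-fold, and their fold changes matched those found here. The correlation across genes was 0.99974 and 0.99985 in KYSE 150 and 0.99976 and 0.99977 in KYSE 510, and 0 genes were called in opposite directions. Their table listed 2000 genes up and 2491 down against the untreated control cells and 2419 up and 1789 down within the knockout in KYSE 150. In KYSE 510 it listed 1659 up and 2427 down, and 1405 up and 2464 down.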

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

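Of the tests in this part, the label swap, the state of the sgNC cultures, the transcription of long genes and the fragment size were chosen only after the results were seen. The results below stood out because the effect of a treatment differed between the groups compared, by a test of the difference itself. In KYSE 150 the interaction of MAGEA6-KO and cisplatin held 8998 genes past the threshold, with medians of -1.92 for S phase, -1.96 for G2/M, -1.70 for crosslink and homologous recombination repair, 1.03 for basal keratinocyte and 1.15 for integrated stress response genes. In KYSE 510 it held 2185 genes, with medians of -0.53 for the unfolded protein response and -0.33 for the integrated stress response. A stress state of the untreated KYSE 510 knockout cultures alone cannot be told from such an interaction. The knockout effect differed between the lines in 9446 genes, with medians of 2.44 for G2/M, 2.14 for S phase, 1.73 for repair, 1.21 for heat shock, -1.98 for basal keratinocyte, -1.54 for integrated stress response, -1.73 for interferon-stimulated and -0.31 for hypoxia genes. The cisplatin effect differed in 8263 genes, with medians of 1.755 for G2/M, 0.62 for repair, -0.90 for basal keratinocyte and -1.21 for integrated stress response genes. There dose and line cannot be separated. Both line differences also rest on the KYSE 150 sgNC libraries, whose state cannot be told from an effect of the knockout or of cisplatin.

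The first pattern weighed was a low cell cycle in the KYSE 150 sgNC libraries, where MKI67, a marker of cycling cells, held 85.0 ± 18.4 CPM against 338 ± 38.3 with cisplatin, 302 ± 9.16 in the knockout and 335 ± 11.95 with both. A swap of labels with the untreated knockout libraries was argued against. With all 24 libraries scaled together, the lowest sgNC value of MAGEA6 was 5.20 times the highest value there. MAGEA6 cannot tell sgNC from the knockout with cisplatin, where it held 98.6 to 112 CPM against 102 to 124 in sgNC. Swaps with the treated groups were not tested. KYSE 510 cells in the sgNC libraries were argued against too, since 98.5% of the genes that best separate the lines lay on the KYSE 150 side. A state of the sgNC cultures, such as crowding, stays open, since the covariance of both sets of fold changes against sgNC was 65.8 times its value in simulated groups without change, which a real effect common to the knockout and cisplatin may give as well. At the preset correlation the comparisons of KYSE 150 that leave out sgNC went both ways, with G2/M genes higher in the knockout under cisplatin (camera, adjusted p = 6.19e-05; adjusted p = 0.439 with an estimated correlation) and lower with cisplatin in the knockout (adjusted p = 0.00423; adjusted p = 0.400 with an estimated correlation). An effect of the knockout and of cisplatin on the cycle therefore cannot be told from a state of the sgNC cultures.

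The second pattern was the fall of long genes under cisplatin. Length, GC content and level of the mature transcript were argued against: with these in the fit, at least 111% of the coefficient of genomic span was kept in the 4 cisplatin comparisons. Other properties of the mature transcript were not in the fit and were not tested. Less complete transcription of long genes in treated cells stays open, since its test, a coefficient per unit of log10 span of -0.96 or lower in all 4 cisplatin comparisons, only restates the pattern. The coefficients were -0.96 and -1.06 in KYSE 150 and -1.08 and -1.12 in KYSE 510, against -0.10 and -0.058 for the knockout without cisplatin. Platinum adducts that stop RNA polymerase more often in longer genes would be a candidate explanation, but counts of mature transcripts cannot show this.

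The third pattern was that short transcripts, ribosomal proteins among them, were high in KYSE 150 MAGEA6-KO with cisplatin replicate 3. Reads from KYSE 510 were argued against, since 100% of the separating genes lay on the KYSE 150 side. A difference in the fragment sizes kept stays open: the correlation of the deviation of this library from its group mean with transcript length was -0.27, but KYSE 510 cisplatin replicate 1 had a lower one, -0.33, and replicate 1 of the KYSE 150 group itself lay further out on the other side, at 0.36. Deviations from a mean of 3 sum to 0, so a deviation of replicate 1 alone would move replicate 3 too. No biological explanation was tested, since the design gives none for a single library.

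Whether other splits of the libraries give as many genes was counted for each comparison. For the interactions 1 of 100 splits, the real one, gave as many genes: 8998 in KYSE 150, with 7024 as the highest other, and 2185 in KYSE 510, with 1133. For the line differences it was 1 of 60, with 9446 against 8851 for the knockout and 8263 against 7992 for cisplatin. A random grouping was argued against for these 4 only as the source of the group differences within the arms. Splits that mix groups within an arm also widen its spread, which lowers their counts, so they cannot decide about the difference between the arms. The high other values came from splits that kept one of the real arms, and splits that kept neither gave at most 2 genes. Comparisons of 3 against 3 allow only 10 splits, too few for a share under 0.05. There, fits of the 6 libraries gave, real against highest other, 10679 against 0 for the knockout, 11290 against 0 for cisplatin, 8534 against 2 for the knockout under cisplatin and 11161 against 0 for cisplatin in the knockout in KYSE 150. In KYSE 510 the same pairs were 3273 against 2, 10752 against 0, 2909 against 2 and 11797 against 0.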

How the results depend on the processing

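In this part the tests of the lists without KYSE 150 MAGEA6-KO with cisplatin replicate 3 were chosen only after the results were seen. Counts of genes past the threshold were taken again with DESeq2 size factors, upper-quartile factors, no filter and the filter of 1 CPM in 3 libraries. They were also taken with DESeq2, limma-voom and the replicate block, and where it applied with a fit of 6 libraries (8 counts) or of all 24 (10 counts). Every count so obtained stayed within 1.5 times the reported one. Leaving out a library moved 1 of the 12 counts further, that of KYSE 510 MAGEA6-KO against sgNC: it was 2272 with all libraries and ran from 1321 to 1910, lowest without MAGEA6-KO replicate 1 (1321), sgNC replicate 1 (1339), sgNC replicate 2 (1344) and MAGEA6-KO replicate 3 (1431). Fewer libraries give wider errors, and which of them drives the fall was not tested. In KYSE 150 the counts ran from 10225 to 10415 for the knockout, 10707 to 11226 for cisplatin, 7309 to 8030 for the knockout under cisplatin, 10687 to 10942 for cisplatin in the knockout and 8366 to 8894 for the interaction. In KYSE 510 they ran from 10937 to 11438 for cisplatin, 2788 to 4352 for the knockout under cisplatin, 10755 to 10846 for cisplatin in the knockout and 1476 to 2906 for the interaction. The line differences ran from 8965 to 9199 for the knockout and 7735 to 8223 for cisplatin.

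No named gene reversed under any alternative. With DESeq2 as the test 1648 values of named genes kept their side of the threshold, 19 passed newly and 3 no longer passed, and with limma-voom the numbers were 1657, 15 and 12. In simulated data for the knockout, DESeq2 called 27 false genes in KYSE 150 and 31 in KYSE 510, edgeR 6 and 5. Scaling moved the zero: upper-quartile factors shifted the median fold change by -0.17 for the KYSE 150 knockout, +0.17 for cisplatin in the KYSE 150 knockout, +0.20 for the KYSE 150 interaction, -0.13 for cisplatin in KYSE 510 and -0.14 for cisplatin in the KYSE 510 knockout. In the KYSE 150 interaction this raised the share of called genes that were positive from 47.2 to 59.6%. The direction of no list called in the text flipped with scaling, but the G2/M list in KYSE 510 knockout cells under cisplatin, the p53 list in KYSE 150 under cisplatin and others with medians near 0 changed sign.

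The largest dependence of the list tests was on the correlation between genes: 139 calls at the preset correlation did not pass with an estimated one and 247 results kept their side. The filter of 1 CPM in 3 libraries lost 7 list calls and gained 1, DESeq2 size factors lost 1 and gained 4, and the replicate block lost 3 and gained 3. Without KYSE 150 MAGEA6-KO with cisplatin replicate 3 the ribosomal list still passed in the knockout under cisplatin (47 genes higher, median 0.58 against 0.80). Of the other lists, that of MAGE and other cancer-testis genes then passed there (adjusted p = 0.0185, from 0.0695), as did oxidative phosphorylation for cisplatin in the knockout (adjusted p = 0.0323, from 0.13).

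The replicate numbers gave no sign of pairing in KYSE 150, where 0 of 12 libraries were closest to one of their own number in another group. In KYSE 510 8 of 12 were, and the highest correlation between libraries was 0.068 with the same number and 0.033 with different ones, so a weak pairing stays open there. With the number as a block, 1669 values of named genes kept their side of the threshold, 12 lost it and 3 gained it.

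For genes with a mean of at least 5 CPM the agreement of effects moved in 4 of 8 pairs. The cisplatin effects without and with the knockout in KYSE 510 correlated at 0.94, those of the lines at 0.72, and those within the knockout of the lines at 0.48 (0.32 over all genes). The knockout effects under cisplatin between the lines correlated at 0.016 over all genes and -0.022 over these, a change of sign around 0 whose cause was not tested. The alternative pseudocount, meant for a table without counts, was not run. In simulated data with far fewer changed genes, edgeR recovered 40.3% of genes at a true log2 change of 0.5 in KYSE 150 and 53.7% in KYSE 510. How often such effects were missed in the real comparisons was not tested.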

Other observations

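Genes of energy metabolism differed between KYSE 150 knockout cells and the sgNC libraries, which stood apart from the other groups of the line. Nuclear-encoded oxidative phosphorylation genes rose in untreated MAGEA6-KO cells in 33 of 37 genes (33 adjusted over the list alone), median 0.83. Glycolysis genes rose in 14 of 22 genes (14 adjusted over the list alone), median 0.92 (camera, adjusted p = 1.63e-05 and 0.000217, and adjusted p = 0.459 and 0.131 with an estimated correlation). In the knockout under cisplatin, without sgNC, the first list was higher in 26 of 37 genes (28 adjusted over the list alone), median 0.45. Glycolysis genes there were higher in 10 of 22 and lower in 7 of 22, median 0.059 (camera, adjusted p = 0.000287 and 0.377, and adjusted p = 0.514 and 0.641 with an estimated correlation). In the untreated KYSE 510 knockout against sgNC the first list fell in 12 of 37 genes (19 adjusted over the list alone), median -0.20, and the second rose in 9 of 21 genes (11 adjusted over the list alone), median 0.17 (camera, adjusted p = 2.19e-08 and 1.27e-05; adjusted p = 0.242 and 0.0920 with an estimated correlation). Mitochondrially encoded mRNAs, which are made by a separate polymerase, fell with cisplatin in 12 of 13 genes (12 adjusted over the list alone) in KYSE 150, median -0.95 (camera, adjusted p = 0.000699; adjusted p = 0.420 with an estimated correlation), and did not pass in KYSE 510 (adjusted p = 0.364). In KYSE 150 8 of 13 (8 adjusted over the list alone) were also lower in the untreated knockout than in the same sgNC libraries, median -0.53 (camera, adjusted p = 0.0986). Within knockout cells 11 of 13 (11 adjusted over the list alone) fell with cisplatin, median -0.99 (camera, adjusted p = 0.000279; adjusted p = 0.323 with an estimated correlation). The share of mitochondrial transcripts in all counts was 6.02 to 6.47% in the sgNC libraries and 3.52 to 3.73% in the untreated knockout. Genes of antigen presentation by MHC class I were higher in the knockout than without it under cisplatin, in 12 of 17 genes (12 adjusted over the list alone) in KYSE 150, median 0.50, and 10 of 17 genes (12 adjusted over the list alone) in KYSE 510, median 0.20 (camera, adjusted p = 1.58e-05 and 0.000270; adjusted p = 0.192 and 0.188 with an estimated correlation). Without cisplatin they were lower in the KYSE 150 knockout in 11 of 17 genes (11 adjusted over the list alone), median -0.68 (camera, adjusted p = 0.0297; adjusted p = 0.459 with an estimated correlation). YAP and TGF-beta responsive genes fell with cisplatin in KYSE 150 knockout cells in 15 of 24 genes (15 adjusted over the list alone), median -0.49 (camera, adjusted p = 0.000117; adjusted p = 0.152 with an estimated correlation).

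Cisplatin against sgNC left several lists without a call. Genes of platinum uptake and efflux did not pass camera, at a median of -0.35 in KYSE 150 and -0.073 in KYSE 510 (adjusted p = 0.212 and 0.169). Single members changed both ways: in KYSE 150 5 of 18 (5 adjusted over the list alone) rose and 9 of 18 (9 adjusted over the list alone) fell. In KYSE 510 7 of 19 (7 adjusted over the list alone) rose and 8 of 19 (8 adjusted over the list alone) fell. ABCC4 (-1.88 ± 0.14 and -1.63 ± 0.081) and MVP (-1.19 ± 0.096 and -1.74 ± 0.081) fell in both lines. Nucleotide excision and translesion repair genes did not pass camera either. Of these 9 of 27 (9 adjusted over the list alone) rose and 12 of 27 (12 adjusted over the list alone) fell in KYSE 150 (adjusted p = 0.890) and 11 of 27 (11 adjusted over the list alone) rose and 9 of 27 (9 adjusted over the list alone) fell in KYSE 510 (adjusted p = 0.969). The median of the latter list in KYSE 510 turned from 0.10 to -0.030 with upper-quartile factors. Ferroptosis genes split in the same way, 10 of 20 (10 adjusted over the list alone) up and 8 of 20 (8 adjusted over the list alone) down in KYSE 150 and 11 of 23 (12 adjusted over the list alone) up and 9 of 23 (9 adjusted over the list alone) down in KYSE 510 (camera, adjusted p = 0.961 and 0.886). Of squamous differentiation genes 11 of 21 (11 adjusted over the list alone) fell and 3 of 21 (3 adjusted over the list alone) rose with cisplatin in KYSE 150. In KYSE 510 11 of 26 (11 adjusted over the list alone) fell and 9 of 26 (9 adjusted over the list alone) rose. The list passed in neither line (camera, adjusted p = 0.212 and 0.415). Epithelial-mesenchymal transition genes did not pass either (camera, adjusted p = 0.477 and 0.847), and autophagy and lysosome genes fell with the knockout in KYSE 150 in 18 of 31 genes (18 adjusted over the list alone), median -0.49 (camera, adjusted p = 0.00520; adjusted p = 0.216 with an estimated correlation).

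Genes used as markers of other cell types were tested as well. In the KYSE 510 knockout 2 of 6 (2 adjusted over the list alone) endothelial markers rose, median 1.29, and with cisplatin in KYSE 510 the list did not pass (camera, adjusted p = 0.000206 and 0.279; adjusted p = 0.0345 and 0.438 with an estimated correlation). Of the fibroblast markers 2 of 6 (2 adjusted over the list alone) fell in the KYSE 510 knockout and none rose (camera, adjusted p = 0.0422; adjusted p = 0.168 with an estimated correlation). Leukocyte markers did not pass (adjusted p = 0.962 in KYSE 150 and 0.377 in KYSE 510).

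The fold changes of the knockout and of cisplatin against the same sgNC libraries correlated at 0.52 in KYSE 150 and 0.088 in KYSE 510, where groups without change gave 0.50 in simulation because of the shared controls. These values cover only genes with a mean of at least 5 CPM in sgNC, 11342 in KYSE 150 and 11445 in KYSE 510. Their covariance was 0.735 in KYSE 150 against 0.0112 in simulation and 0.0262 against 0.00926 in KYSE 510. After subtraction of the simulated covariance, 0.724 remained in KYSE 150 and 0.017 in KYSE 510. Controls of 3 libraries cannot be split into 2 sets of 2, so the correlation itself was not freed of the shared part.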
